A study of Mus musculus with 2 samples.

How the data were processed

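Chromatin of mouse hearts at embryonic day 16.5 (strain B6NCrl, pools of both sexes) was immunoprecipitated for H3K4me2 and sequenced, with a size range of 300 to 500 bp. Per the labels, there are 2 biological replicates from separate pools of tissue, so the single group has n = 2 and no comparison between conditions exists. The pool of replicate 2 held 41 hearts, and the number for replicate 1 is not given.

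The deposited files are 4 lists of called peaks on mm10: one for each replicate, one called on the alignments of both together (the pooled list) and one that the authors derived from the pooled list and both replicates' lists (the replicated list). The aligner and the peak caller are not given in the sources used here. Each peak has 3 values from the authors: a fold enrichment (a ratio), a −log10 p and a −log10 q, and none was recomputed. The lowest −log10 p in each list lies just above 2, the value of a p of 0.01. Per the labels, the list of replicate 1 was derived from its alignments and 2 further files of unknown kind, and that of replicate 2 from its alignments and 1 further file. The lists hold no read counts, so the depth per sample is unknown and no counting interval could be given. Differences between the replicates in number and length of peaks can therefore not be separated from depth.

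Peaks on chromosomes 1 to 19 and X were used, which left 71674 in replicate 1, 62180 in replicate 2, 63175 pooled and 54696 replicated, with coordinates printed from 1. Genes were the protein-coding records of GENCODE M21 on GRCm38.p6, 21755 in number, of which 27 with a repeated name were left out and 21728 used. The TSS is the annotated 5' end of the gene. A promoter peak overlaps the 1 kb on either side of it, and the covered length is the number of bases under peaks within 10 kb on either side, per replicate. Each peak was given 1 genomic class, taken in the order promoter, exon, intron, intergenic. The classes rest on protein-coding genes, so non-coding genes outside them count as intergenic. As a background, the peaks of 1 replicate were rotated 100 times along their chromosomes, those of replicate 1 for genomic classes and those of replicate 2 for overlap. Domains were bases shared by both replicates, joined across gaps of up to 1 kb. Log2 ratios of covered length had 100 bp added to both values. Overlap meant 1 bp unless stated.

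The 25 gene lists were written from general knowledge of the cell types: contractile genes, cardiac transcription factors, calcium handling and conduction, atrial, ventricular, energy metabolism, endothelial and endocardial, smooth muscle and pericyte, fibroblast and valve mesenchyme, epicardial, erythroid, macrophage and leukocyte, neural crest with Schwann and autonomic, signalling by Notch, BMP and TGF-beta, cell cycle, housekeeping, transcription factors of other lineages, hepatocyte, lung and foregut, skeletal muscle, neuron, kidney and gut, germ cell, Hox and olfactory receptor genes. The median covered length of a list, as the mean of the replicates, was placed among 10000 random lists of other protein-coding genes. These were drawn with replacement within 10 classes of promoter CpG content. CpG content here is the ratio of observed to expected CpG pairs in the 500 bp on either side of the TSS. This resampling of genes is called the gene permutation test in the text. It draws single genes, so it does not match clusters of genes that share bases. With overlapping windows joined, 39 Hox genes form 9 blocks and 1134 olfactory receptor genes 631. Windows also overlap among erythroid (19 genes in 16 blocks), macrophage (18 in 16), hepatocyte (18 in 16), skeletal muscle (18 in 17), germ cell (14 in 13) and energy genes (23 in 22). The 2-sided p of the gene permutation test was adjusted over the 25 lists by Benjamini-Hochberg with a threshold of 0.05. The smallest p that the test can give is 0.0002. Promoter peaks in both replicates were compared between a list and all other genes by Fisher's exact test, adjusted in the same way. Differences between replicates were placed among random lists drawn without matching on CpG, as percentiles without a test. Several comparisons were added after the data were seen. Among them were promoter peaks against random lists matched on CpG, and replicate ratios with each base counted once. For the latter, the windows of a list were joined into blocks and set against random blocks of the same length. This was done with and without matching on the strength of pooled peaks. The closing sections name the others.

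The 16 sequence patterns (7 of heart regulators) were searched on both strands in 500 bp around the summits of peaks over 2.5 kb from any protein-coding TSS, and in windows 5 kb away on either side that held no peak. Each was also searched with its letters reversed, which keeps letter content but not CpG pairs. The patterns were AGATAAG (GATA), CTAWWWWTAR (MEF2), GGAATGY (TEAD), AGGTGTGA (TBX), TYAAGTGS (NKX2), CCWWWWWWGG (SRF), TCAAGGTCA (ESRR), MCGGAAGY (ETS), TGASTCA (AP-1), CCASYAGRKGGC (CTCF), CAGCTG (E-box), GTTAATNATT (HNF1), CAAAGTCCA (HNF4), ATGCAAAT (OCT4), GCAGATGGY (neuronal E-box) and GTTGCCATGG (RFX). Matches per kb in gaps of 100 to 600 bp between neighbouring distal peaks were set against the flanking peaks. After the data were seen, CTCF and MEF2 were also set against up to 200 patterns with their letters in random order, once with any order and once with orders that cannot hold a CpG.

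Named genes were chosen by a rule. From each list except Hox and olfactory receptor genes, the 2 with the largest covered length and the first without a promoter peak in both replicates were named. A fixed set was always named: Nkx2-5, Gata4, Tbx5, Hand2, Mef2c, Myh6, Myh7, Tnnt2, Nppa, Actc1, Alb, Neurod1, Pou5f1, Myod1 and Sftpc. Added to these were the 5 widest domains, the 5 replicated peaks with the highest fold enrichment, and the 5 genes with the largest log2 ratio between replicates in each direction among genes with at least 2 kb covered. The lists, patterns, this rule and the alternatives were set before the data were examined, except where the text says otherwise.

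The tests were checked on simulated data with lists of 20 genes. Without an effect, 3% of 100 lists passed the gene permutation test, and 40%, 80% and 100% of 20 lists did when covered length was multiplied by 1.5, 2 and 3. All these lists were adjusted together, with 2000 random lists each. Covered lengths were shuffled within CpG classes, so bases shared by neighbouring genes were not covered. The rates therefore need not hold for the 25 lists. With Fisher's exact test 2% of 100 lists passed without an effect, and 75% of 20 lists when promoter peaks were at 95% of genes. Every gene without an effect had the same chance of a promoter peak there, so calls due to CpG content were not covered. Of the 16 patterns, 0 gave matches that differed from a regular expression search. Alternatives covered the overlap rule, −log10 q of at least 2 and of at least 5, windows around the TSS of 500 bp and 2.5 kb (promoter) and of 5 and 25 kb (covered length), all transcripts' starts, no CpG matching, the pooled and replicated lists, each replicate left out, distal limits of 1 and 10 kb, motif windows of 200 bp and 1 kb, and gaps of 100 to 300 and 300 to 1000 bp. Peaks on chromosome Y and unplaced contigs were left out of the comparisons. Software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Matplotlib 3.10.9 and bedtools 2.31.1.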

Results

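Dimethylation of histone H3 at lysine 4 (H3K4me2), a mark of promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in mouse hearts at embryonic day 16.5. The series held 1 group of 2 biological replicates, each a pool of hearts from embryos of both sexes. The pool of replicate 2 came from 41 embryos, and the number behind replicate 1 was not given. No second tissue, stage or treatment was included, so the comparisons were between the replicates, between the replicates and the authors' pooled and replicated lists, and between genes or regions within the lists. The deposited files held called peaks on mm10, 71702 for replicate 1 and 62197 for replicate 2, and no read counts, so the sequencing depth was unknown. On chromosomes 1 to 19 and X the peaks covered 61.4 Mb in replicate 1 and 49.2 Mb in replicate 2, with median widths of 505 and 486 bp. Values with an error are the mean ± SD of the 2 replicates unless stated otherwise.

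Genes of the heart muscle lay in long stretches of H3K4me2. The length covered by peaks within 10 kb of the annotated 5' end of the gene had a median of 1934 bp over 21728 protein-coding genes. Among 25 contractile genes of the cardiomyocyte, the median was 8492 bp, against 896 bp in random genes with the same promoter CpG content. Myh7, the beta myosin heavy chain (chromosome 14, 54970684 to 54994626), was covered over 15230 ± 1345 bp (SD, n = 2). The ventricular myosin light chain gene Myl2 had 10988 ± 767 bp, the alpha myosin heavy chain gene Myh6 10224 ± 1162 bp, the cardiac actin gene Actc1 10173 ± 1379 bp and the troponin T gene Tnnt2 9716 ± 721 bp. All 25 contractile genes had a peak within 1 kb of the 5' end in both replicates. Cardiac transcription factors had a median of 8384 bp, against 2426 bp in matched random genes. The longest were Hand2 (chromosome 8, 57320983 to 57324633) with 18461 ± 484 bp and Nkx2-5 (chromosome 17, 26838664 to 26845009) with 16874 ± 1137 bp, both regulators of heart formation. Tbx5 had 13444 ± 1590 bp and Gata4 11151 ± 888 bp. Of the 27 factors, 25 had a promoter peak in both replicates, and Mef2c and Smyd1 did not. Mef2c was covered over 0 bp in both replicates around its annotated 5' end (chromosome 13, position 83504034).

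Calcium handling and conduction genes had a median of 6183 bp, against 2032 bp in matched random genes, and 21 of 23 had a promoter peak in both replicates. Gja1, which encodes the gap junction protein connexin 43, had 10730 ± 928 bp, and the sodium-calcium exchanger gene Slc8a1 10077 ± 1796 bp. Sln, the sarcolipin gene, was covered over 245 bp in replicate 1 and 0 bp in replicate 2. Ventricular genes had a median of 7688 bp, against 1657 bp, and 10 of 10 had a promoter peak in both replicates. Of these, Myh7, Myl2 and Myl3 are also in the contractile list and Irx4, Hey2 and Hand1 also among the cardiac factors. Energy metabolism genes had a median of 4517 bp, against 1995 bp, and 22 of 23 had a promoter peak. The longest were Acadvl, for an enzyme of fatty acid oxidation, with 7163 ± 322 bp and the muscle creatine kinase gene Ckm with 6768 ± 919 bp, while the myoglobin gene Mb had 0 bp at its annotated 5' end. Atrial genes had a median of 3524 bp, against 1785 bp, with Tbx5 and the nuclear receptor gene Nr2f2 (12129 ± 909 bp) the longest. Both are also among the cardiac factors, while Sln, Gja5 and Kcnj3 are also in the calcium list and Myl4 and Myl7 in the contractile list. Nppa, the atrial natriuretic peptide gene (chromosome 4, 148000722 to 148002079), had 1512 bp and a promoter peak of fold 4.06 in replicate 1, and 0 bp and no promoter peak in replicate 2.

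Each of the 6 heart lists exceeded its random lists in the gene permutation test. The contractile, transcription factor, calcium, ventricular and energy lists lay above all 10000 random lists, with adjusted p = 0.000714 in the permutation test, from p = 0.0002, the smallest that it can give. The atrial list lay at percentile 99.2 with adjusted p = 0.0337 in the permutation test. Its call was lost with a 25 kb window, with stricter q thresholds and in replicate 2 alone, where the adjusted p of the permutation test was 0.364, 0.0517, 0.0621 and 0.0996. In all 6 lists the median of each replicate lay above the median of the random lists. Genes are not replicates, so percentiles and p-values of gene lists describe these 2 libraries. Lists that share members are also not independent of each other.

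**Figure D1:**
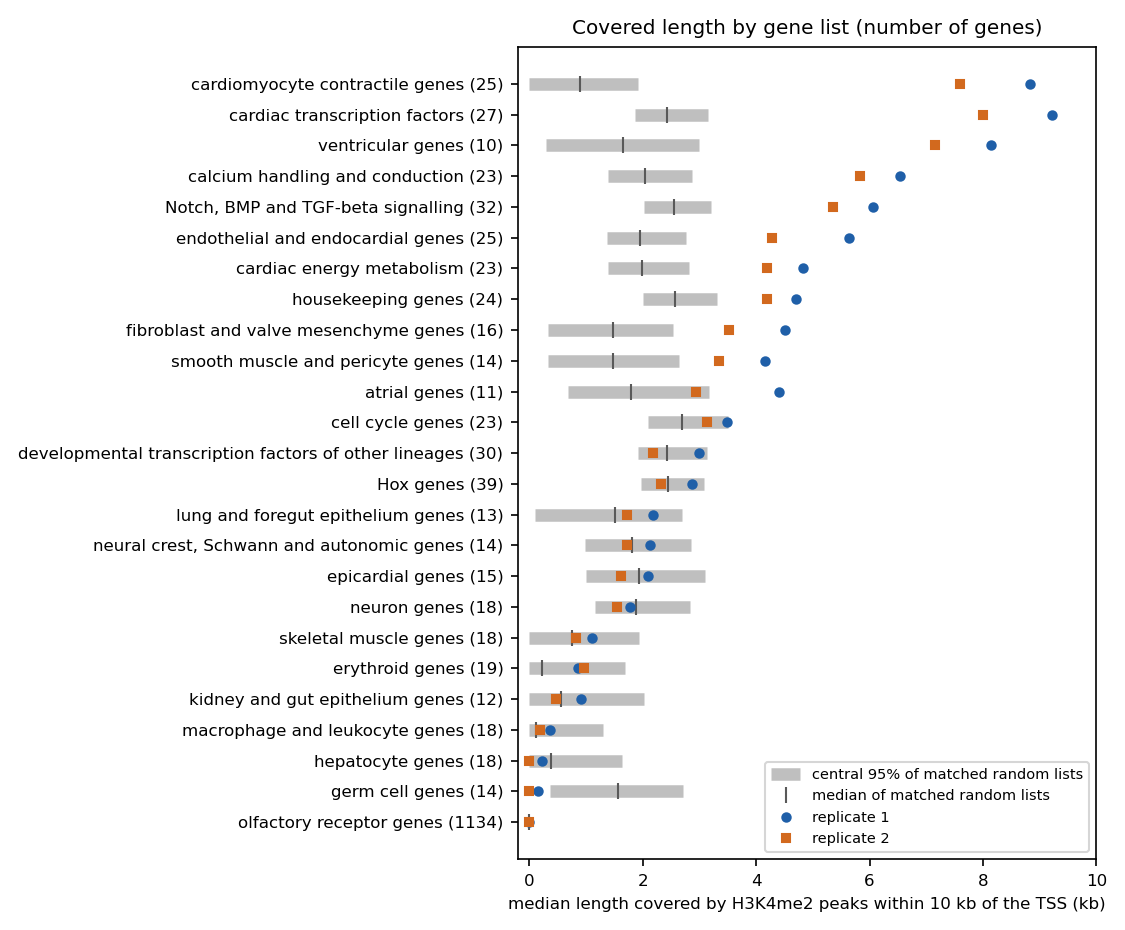
Median length in kb covered by H3K4me2 peaks within 10 kb of the 5' end (TSS, x axis) for the 25 gene lists (y axis, number of genes in brackets), for replicate 1 (circles) and replicate 2 (squares), with the median (tick) and the central 95% (grey bar) of 10000 random lists matched on promoter CpG content. The contractile list lies at 8.49 kb for the mean of the replicates and its random lists at 0.896 kb.

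Vessel, stromal and signalling genes also carried long H3K4me2 regions, while epicardial, erythroid, macrophage and neural crest genes did not pass the test against random genes. Endothelial and endocardial genes had a median of 4760 bp, against 1954 bp in matched random genes. Dll4, a Notch ligand of arterial endothelium, had 11742 ± 1055 bp and Nfatc1, a regulator of endocardial cells and valves, 10828 ± 101 bp. Cdh5, the gene of VE-cadherin, had 6322 bp with a promoter peak in replicate 1 and 3197 bp with none in replicate 2. Smooth muscle and pericyte genes had a median of 3814 bp against 1480 bp, with Myocd at 9237.5 ± 598 bp and Cspg4 at 6442 ± 1438 bp. Myocd is also among the cardiac factors. Fibroblast and valve mesenchyme genes had a median of 4016 bp against 1472 bp, with the receptor gene Pdgfra at 9074.5 ± 904 bp and the collagen gene Col1a1 at 7517.5 ± 2139 bp. The collagen gene Col3a1 had 2327 bp in replicate 1 and 1568 bp in replicate 2, with a promoter peak in replicate 1 only. Notch, BMP and TGF-beta signalling genes had a median of 5530 bp against 2547 bp, led by the inhibitory Smad gene Smad7 with 12006 ± 421 bp. Rbpj, the DNA-binding partner of Notch, had 1731 ± 38.2 bp and no promoter peak at its annotated 5' end.

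These 4 lists passed the gene permutation test, but they are not independent. Notch1 and Dll4 are in both the endothelial and the signalling list, and Notch3 in both the smooth muscle and the signalling list. The endothelial and the signalling list lay above all random lists, with adjusted p = 0.000714 in the permutation test. For fibroblast genes the adjusted p was 0.00111 and for smooth muscle genes 0.0045. Epicardial genes had a median of 1825 bp against 1926 bp and did not pass (permutation adjusted p = 0.904), although Tbx18 had 9796.5 ± 1189 bp and Wt1 8990 ± 1561 bp. Tbx18 is also among the cardiac factors. Upk3b, a marker of mesothelium, had 0 bp. Erythroid genes had a median of 911.5 bp against 224 bp (permutation adjusted p = 0.662), with Tal1 at 7455 ± 1290 bp and Klf1 at 4615.5 ± 371 bp, and Gata1 at 0 bp. Tal1 is also in the endothelial list. Macrophage and leukocyte genes had a median of 332 bp against 109 bp (permutation adjusted p = 0.843). Their longest members, Cd68 with 5454.5 ± 448 bp and Tyrobp with 3546.5 ± 204 bp, had no promoter peak of their own, and Ptprc, the gene of CD45, had 892 bp in replicate 1 and 203 bp in replicate 2. Neural crest, Schwann and autonomic genes had a median of 1926 bp against 1809 bp (permutation adjusted p = 0.904), with Ednrb at 5803 ± 1549 bp, Tfap2a at 4681.5 ± 694 bp and Sox10 at 357.5 ± 141 bp.

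Among general genes, the housekeeping list had a median of 4425 bp against 2562 bp (permutation adjusted p = 0.00111), with the elongation factor gene Eef2 at 8066.5 ± 480 bp and the ribosomal gene Rpl13a at 7190.5 ± 1146 bp. Ywhaz, which had no peak at its annotated 5' end, was covered over 4424.5 ± 1370 bp. Cell cycle genes had a median of 3245 bp against 2695 bp (permutation adjusted p = 0.296), with Cdc20 at 7286 ± 696 bp and the mitotic kinase gene Aurkb at 6934 ± 1020 bp. With a 5 kb window or without matching on CpG the cell cycle list passed, with adjusted p = 0.0246 and 0.0158 in the permutation test.

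Within 10 kb, no list of genes of other organs exceeded random genes of the same CpG content in the gene permutation test. Germ cell genes had a median of 74.8 bp against 1567 bp and were covered over less than random (permutation adjusted p = 0.0337). The longest of them were Ddx4 with 1695.5 ± 432 bp and the pluripotency gene Nanog with 1371.5 ± 67.2 bp. Hepatocyte genes had a median of 109 bp against 382 bp. Alb, the albumin gene, had 0 bp in both replicates, and the longest were Foxa3 with 2469.5 ± 13.4 bp and Proc with 2123.5 ± 398 bp. Skeletal muscle genes had a median of 966 bp against 747.5 bp. Tnnt1, a slow skeletal troponin gene, had 9848 ± 1262 bp, with a promoter peak of fold 6.15 in replicate 1 and 5.32 in replicate 2. Covered length counts any peak within 10 kb, and bases at neighbouring genes were not told apart from those of Tnnt1. Mylpf had 5957.5 ± 1438 bp, Myf5 1314 ± 238 bp without a promoter peak and the muscle regulator Myod1 400.5 ± 305 bp. Neuron genes had a median of 1724 bp against 1874 bp, with Eomes at 3968.5 ± 472 bp, Neurod2 at 3527.5 ± 380 bp and Neurod6 at 739.5 ± 30.4 bp. Kidney and gut epithelium genes had a median of 685.5 bp against 559 bp, with Cdh16 at 4749.5 ± 559 bp without a promoter peak, Lgr5 at 2672.5 ± 264 bp and Slc12a1 at 0 bp. Lung and foregut epithelium genes had a median of 1956 bp against 1519 bp, with Foxa1 at 4765.5 ± 1918 bp. Sftpc, the surfactant protein C gene, was covered over 4977.5 ± 2012 bp by peaks outside its own promoter.

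Developmental transcription factors of other lineages had a median of 2643 bp against 2427 bp. The longest were Pax6 with 4698 ± 776 bp and Neurog2 with 4222 ± 771 bp, Neurod1 had 1202.5 ± 295 bp, Pax8 had 635 ± 126 bp, and the pluripotency factor Pou5f1 had 1821.5 ± 19.1 bp without a promoter peak. Hox genes had a median of 2491 bp against 2440 bp. The adjusted p of the permutation test lay between 0.681 and 0.904 for the hepatocyte, skeletal muscle, neuron, kidney and gut, lung, other-lineage and Hox lists. The 1134 olfactory receptor genes had a median of 0 bp, as had their random lists, and 2 of them had a promoter peak in both replicates. The median of the Hox list lay below all random lists within 5 kb and at percentile 99.9 within 25 kb. Hox genes lie in clusters and share bases between their windows, while the random lists draw single genes, so these percentiles are not read as a test. Within 5 kb the other-lineage factors lay below their random lists, with adjusted p = 0.0208 in the permutation test. Without matching on CpG, macrophage and hepatocyte genes also passed as covered over less, with adjusted p = 0.0457 and 0.0331 in the permutation test. Olfactory receptor genes had an adjusted p of 0.000556 in the same permutation test. They also lie in clusters, so this value is not read as a test either. The germ cell call was lost with windows of 5 and 25 kb and at a −log10 q of at least 5, with adjusted p = 0.0543, 0.364 and 0.0614 in the permutation test.

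H3K4me2 stood at the 5' end of most protein-coding genes. A peak within 1 kb of the 5' end was present in both replicates at 14273 of 21728 genes (65.7%), with 14623 in replicate 1 and 14352 in replicate 2. The share rose with promoter CpG content, from 2.95% of genes in the lowest of 10 CpG classes to 99.4% in the highest. By list, every gene had one among contractile (25 of 25), ventricular (10 of 10), smooth muscle (14 of 14) and cell cycle genes (23 of 23), and 24 of 25 endothelial, 15 of 16 fibroblast, 31 of 32 signalling and 23 of 24 housekeeping genes had one. The promoters of macrophage genes (3 of 18), hepatocyte genes (3 of 18), germ cell genes (2 of 14) and kidney and gut genes (4 of 12) mostly lacked a peak. In between were atrial genes (9 of 11), epicardial genes (11 of 15), other-lineage transcription factors (24 of 30), neuron genes (13 of 18), Hox genes (27 of 39), neural crest genes (7 of 14), lung genes (6 of 13), skeletal muscle genes (8 of 18) and erythroid genes (8 of 19). Among the lists with a higher share than other genes by Fisher's exact test (2-sided) the adjusted p ran from 0.000259 for contractile and signalling genes to 0.0319 for ventricular genes, and 11 lists passed. These were the contractile, cardiac factor, calcium, ventricular, energy, endothelial, smooth muscle, fibroblast, signalling, cell cycle and housekeeping lists. The share was lower in 5 lists, macrophage and hepatocyte (both with adjusted p = 0.000227 by Fisher's exact test), germ cell (0.000402), kidney and gut (0.0452) and olfactory receptor genes, which lie in clusters. Calls were lost in Fisher's exact test for fibroblast genes at a 500 bp window and at both stricter q thresholds (adjusted p = 0.0976, 0.0959 and 0.258), for endothelial genes at 500 bp and at the stricter q of 5 (0.187 and 0.0591), and for ventricular genes at 2.5 kb, in the pooled list and in replicate 1 alone (0.0538, 0.0542 and 0.0508). Calls were gained in Fisher's exact test by other-lineage factors, higher at 2.5 kb, in the replicated list, in the pooled list and in replicate 1 alone (adjusted p = 0.0469, 0.0313, 0.0326 and 0.0114). Lower shares were called for skeletal muscle genes at −log10 q of at least 2 and of at least 5 (0.0108 and 0.00467) and for erythroid genes at 500 bp and in replicate 1 alone (0.0309 and 0.0386). At any annotated transcript's start, chosen as an alternative after the data were seen, ventricular, fibroblast and kidney and gut genes did not pass (Fisher's exact test, adjusted p = 0.0555, 0.0525 and 0.246), and Hox genes, which lie in clusters, did with 34 of 39 (0.0256). Fisher's exact test sets a list against all other genes, whatever their CpG content. Against random lists matched on CpG, an alternative added after the data were seen, 7 lists were higher: contractile, calcium, ventricular, energy, endothelial, smooth muscle and fibroblast genes. Lower were germ cell genes, with adjusted p = 0.000833 in this permutation test, from the smallest p that it can give, and Hox and olfactory receptor genes, whose clusters the random lists do not match. Macrophage (percentile 19.9), hepatocyte (5.68) and kidney and gut genes (32.8) did not pass, and neither did cardiac factor, signalling, cell cycle and housekeeping genes.

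Peaks at promoters were wider and higher than the others. They made up 27.1 ± 4.16% of peaks (SD, n = 2), against 1.55% of the genome and at most 2.59% in 100 rotations of the peaks of replicate 1 along their chromosomes. In replicate 1 the median promoter peak was 1532 bp wide with a fold enrichment of 27.3, and the median of the other peaks was 378 bp with 4.24. In replicate 2 the medians were 1195 bp and 21.5 at promoters, and 344 bp and 4.53 elsewhere. Exons held 11.1 ± 0.187% of peaks and 3.27% of the genome, introns 34.1 ± 2.38% and 35.2%, and intergenic sequence 27.7 ± 1.96% and 60.0%. A peak needs only to touch a class, whereas the genome share counts bases, so rotated peaks are the closer background. The rotations of replicate 1 gave means of 7.73% for exons, 31.4% for introns and 58.5% for intergenic sequence. The fold enrichment, −log10 p and −log10 q of a peak are the authors' own values. They were used to describe, rank or filter peaks within a list, and the fold also in the correlation between replicates, in the comparison of height at the TSS and, with width, to match random peaks. The promoter share was 40.5% when the starts of all transcripts of all genes counted, and 40.4% among peaks with a −log10 q of at least 5. The X chromosome had 9.43 peaks per Mb in replicate 1 and 8.86 in replicate 2, and 50.2% of its 948 genes had a promoter peak in both.

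**Figure D2:**
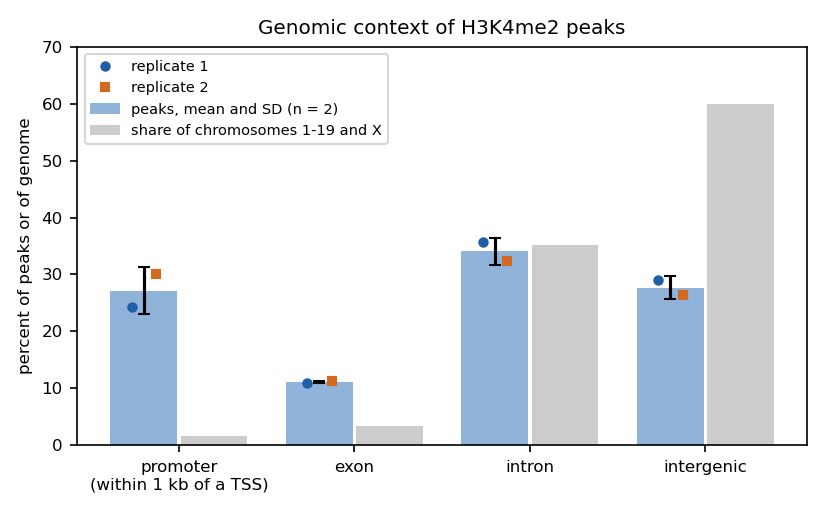
Percent of H3K4me2 peaks in each genomic class (blue bars, mean and SD of the 2 replicates, with replicate 1 as circles and replicate 2 as squares) and percent of chromosomes 1 to 19 and X in that class (grey bars). Promoters hold 27.1% of peaks and 1.55% of the sequence.

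Of the 5 widest H3K4me2 domains, 3 lay at cardiac transcription factor genes and 1 at a myosin gene. After peaks shared by both replicates were joined across gaps of up to 1 kb, there were 38192 domains with a median width of 841 bp, and 60 were over 10 kb. The widest, 25392 bp on chromosome 8 from 57311123 to 57336514, spanned Hand2. Next came a domain of 22791 bp inside Gata4 (chromosome 14, 63230336 to 63253126), with its nearest edge 18566 bp from the annotated 5' end of the gene. The Myh7 domain was 20217 bp wide (chromosome 14, 54978005 to 54998221), and the Nkx2-5 domain 18681 bp (chromosome 17, 26835783 to 26854463). The fifth, of 17326 bp, lay at the 5' end of Meis2, a homeobox gene (chromosome 2, 116055719 to 116073044). The peaks with the highest fold enrichment lay at other genes. In the replicated list these were a peak of 69.3 at the 5' end of Helz (chromosome 11, 107546320 to 107549096), 1 of 68.7 inside Col25a1 (chromosome 3, 130179999 to 130182070), 1 of 68.5 in the non-coding gene Gm36445 (chromosome 13, 65240218 to 65242924), 1 of 67.3 at the 5' end of Plch1 (chromosome 3, 63898071 to 63900490) and 1 of 66.1 at Dleu7 and Rnaseh2b (chromosome 14, 62292322 to 62293443). No replicate-based error can be given for a fold of the replicated list, which the authors derived from both replicates.

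**Figure D3:**
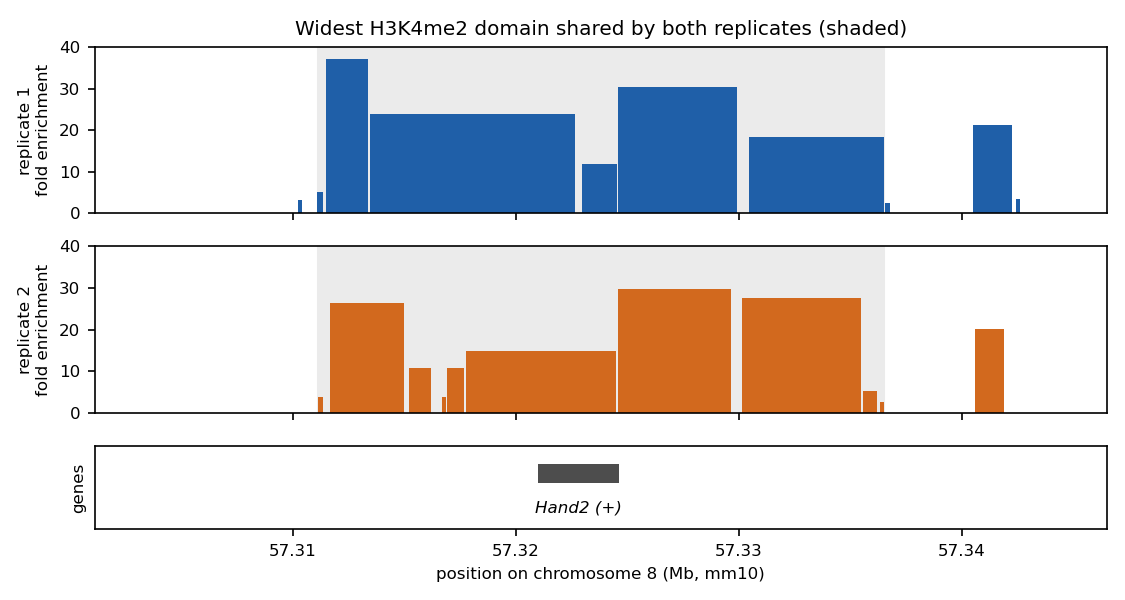
H3K4me2 peaks of replicate 1 (top) and replicate 2 (middle) around Hand2 on chromosome 8, as bars from start to end (x axis, Mb, mm10) with the height of the peak's fold enrichment as the authors gave it (y axis), and the Hand2 gene (bottom, plus strand). The shaded domain, from 57311123 to 57336514, is covered by several neighbouring peaks in both replicates.

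Away from the annotated 5' ends of protein-coding genes, the sequence patterns of CTCF, ETS and MEF2 proteins had the highest ratios of H3K4me2 peaks to flanking windows. Most distal peaks held none of each: CTCF matched in 2.34%, ETS in 4.20% and MEF2 in 8.28% (means of the replicates). The E-box CAGCTG matched in 32.2% and TEAD in 16.4%. In 500 bp around the summits of peaks over 2.5 kb from any protein-coding 5' end (50203 in replicate 1 and 39230 in replicate 2), the pattern of CTCF, which organises chromosome loops, was 5.92 ± 0.461 times (SD, n = 2) as frequent as in flanking windows. Its letters in reversed order, a control for letter content, gave 1.77 ± 0.0189. Reversal does not keep CpG pairs. The reversed CTCF, E-box, neuronal E-box, RFX and OCT4 patterns gain a CpG, the reversed TEAD and NKX2 patterns can hold one, and the reversed ETS pattern loses the fixed one and can hold another. For these 8 the reversed pattern is no control for CpG content. The pattern of ETS factors had a ratio of 2.49 ± 0.101, against 1.10 ± 0.0184 reversed. Among patterns of heart regulators, MEF2 had 1.95 ± 0.108 (0.635 ± 0.0151 reversed), TEAD 1.42 ± 0.0581 (0.921 ± 0.000606 reversed), GATA 1.40 ± 0.0260 (0.792 ± 0.00828 reversed) and NKX2 1.17 ± 0.0139 (0.991 ± 0.0197 reversed). The SRF pattern had 1.05 ± 0.0372 and AP-1 1.11 ± 0.00987, against 0.861 ± 0.00325 and 0.963 ± 0.0266 reversed. The patterns of ESRR (0.872 ± 0.0542) and TBX (0.828 ± 0.000338) were below 1, but ESRR was above its reversed pattern (0.621 ± 0.0399) and TBX below it (1.01 ± 0.0130). Of patterns from other lineages, OCT4 (0.875 ± 0.0108) and HNF1 (0.707 ± 0.00930) were below 1 and above their reversed patterns (0.756 ± 0.0858 and 0.613 ± 0.0201). HNF4 had 0.918 ± 0.00761, against 0.978 ± 0.0884 reversed. The E-box CAGCTG had 1.53 ± 0.00488 (1.58 ± 0.0440 reversed), the neuronal E-box 1.45 ± 0.0352 (1.41 ± 0.250 reversed) and RFX 1.39 ± 0.133 (1.99 ± 0.292 reversed). These ratios were not tested and stand as values with their spread. Distal peaks can still lie at other transcripts' starts or at non-coding genes. Distal from any transcript's start, an alternative chosen after the data were seen, CTCF had 6.41 ± 0.445 and MEF2 2.17 ± 0.0710. In windows of 200 bp the CTCF ratio was 0.963 ± 0.0845 and the SRF ratio 0.991 ± 0.00350, and among peaks with a −log10 q of at least 5 the SRF ratio was 0.987 ± 0.0861. The order of the patterns also changed in 200 bp, with ETS at 2.65 ± 0.143, the E-box CAGCTG at 1.68 ± 0.00436 and MEF2 at 1.47 ± 0.0557.

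The CTCF pattern avoided the summits. Its density, computed after the ratios were seen, was 0.00453 ± 0.000637 matches per kb within 50 bp of the summit, 0.0998 ± 0.000874 at 150 to 200 bp and 0.00887 ± 0.000432 at 400 to 500 bp. MEF2 matches were spread more evenly, with 0.107 ± 0.0103, 0.236 ± 0.00199 and 0.109 ± 0.000862 per kb at the same distances. In gaps of 100 to 600 bp between neighbouring distal peaks (6426 in replicate 1 and 5199 in replicate 2), CTCF matches were 2.92 ± 0.474 times as dense as in the flanking peaks, from 52 and 44 matches. MEF2 matches were 2.03 ± 0.127 times as dense there, but its reversed pattern gave 2.05 ± 0.162. For HNF1 the ratio was 1.73 ± 0.0589 and its reversed pattern gave 1.53 ± 0.303, and the median over the 7 heart patterns was 1.03 ± 0.0893. Reversed CTCF had too few matches for a ratio. Both ratios depended on the width of the gap, with 6.18 ± 1.85 for CTCF and 2.79 ± 0.327 for MEF2 in gaps of 100 to 300 bp, and 0.730 ± 0.0419 and 1.19 ± 0.0958 in gaps of 300 to 1000 bp.

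**Figure D4:**
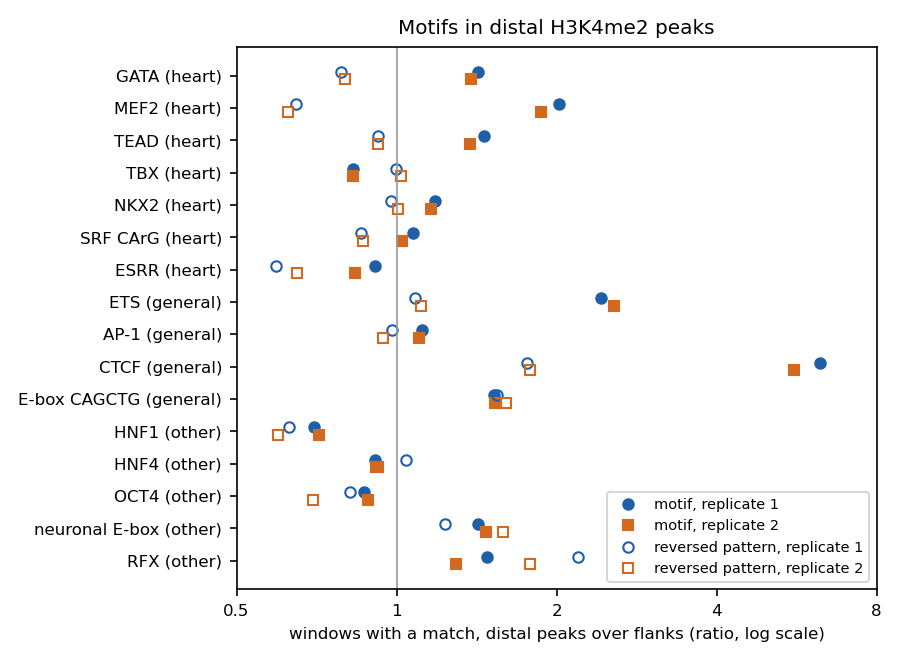
Ratio of windows with a match, distal H3K4me2 peaks over flanking windows (x axis, log scale), for the 16 patterns (y axis) in replicate 1 (filled circles) and replicate 2 (filled squares), with the reversed pattern as open symbols. CTCF lies at 5.92 and its reversed pattern at 1.77, while the E-box CAGCTG lies at 1.53 and its reversed pattern at 1.58.

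**Figure D5:**
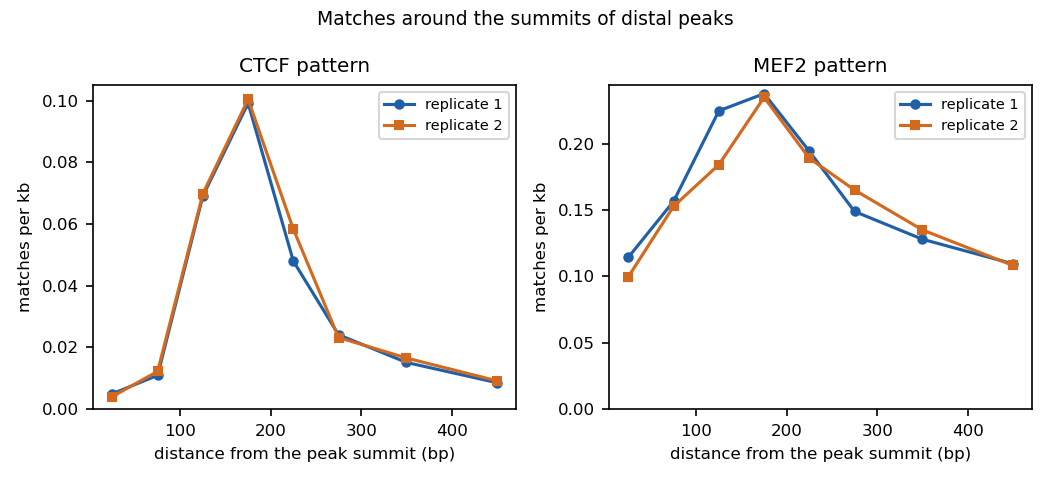
Matches per kb to the CTCF pattern (left) and the MEF2 pattern (right) by distance from the summit of distal peaks in bp (x axis), in replicate 1 (circles) and replicate 2 (squares). CTCF rises from 0.00453 per kb within 50 bp to 0.0998 per kb at 150 to 200 bp.

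The replicates marked much the same genes. Covered lengths around the 21728 protein-coding genes had a Spearman correlation of 0.985, across genes, which are not independent replicates. Of 11251 genes with at least 2 kb covered in either replicate, 37 differed by over 2-fold, and in each of these the length was larger in replicate 1. The largest differences were at Fgf7, a fibroblast growth factor gene, with 2014 bp in replicate 1 and 0 bp in replicate 2, at Cd300lg (2025 and 189 bp), Stmn4 (2223 and 589 bp), the apelin receptor gene Aplnr (3144 and 885 bp) and Zfp366 (3616 and 1108 bp). In the other direction stood Plac8 with 1169 bp in replicate 1 and 2032 bp in replicate 2, Zfp385a (1487 and 2253 bp) and Arpp21 (2514 and 3685 bp). The neighbours Snrnp25 and Il9r, whose windows share their peaks, had 2120 and 2872 bp.

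Gene lists of other organs accounted for most of the lists that differed between the replicates. Over all genes, replicate 2 had a summed length lower by a log2 ratio of −0.21. Relative to that, Hox genes were at −0.39, with 150.6 kb covered in replicate 1 and 99.8 kb in replicate 2 and mean folds of 11.7 and 11.1. Hox genes are clustered, so these sums count shared bases more than once. With each base counted once, their windows form 9 blocks with 79.2 and 53.0 kb, at −0.36. Lung and foregut genes were at −0.36 (29.2 and 19.6 kb, mean folds 22.4 and 21.8), and other-lineage transcription factors at −0.22 (82.5 and 61.1 kb, mean folds 17.0 and 14.0). Much of the lung difference came from Sftpc (6400 bp in replicate 1 and 3555 bp in replicate 2) and Foxa1 (6122 and 3409 bp). Values below the central 95% of random lists were also found for endothelial (−0.16, 148 and 115 kb, mean folds 17.1 and 13.8), neural crest (−0.17, 33.2 and 25.6 kb, mean folds 17.3 and 16.4), germ cell (−0.18, 7.78 and 5.92 kb, mean folds 20.5 and 21.6), skeletal muscle (−0.13, 37.2 and 29.4 kb, mean folds 14.0 and 12.7) and olfactory receptor genes (−0.06, 27.5 and 22.7 kb, mean folds 11.04 and 9.58). The other 17 of 25 lists, contractile genes (−0.01) and cardiac factors (0.01) included, lay within the central 95% of random lists. When the random lists were also matched on the strength of the peaks, an alternative added after the data were seen, 3 of the 8 lists stayed outside, namely Hox, lung and other-lineage factors. With each base counted once and random blocks matched on length and strength, also added later, these 3 lay at percentiles 1.51, 0 and 0.15. Against random peaks matched on fold and width, added later still, lung genes alone of these 3 stayed outside (0.4), with Hox genes at 4.93 and other-lineage factors at 2.85.

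Peak by peak, 67.5% of the peaks of replicate 1 touched a peak of replicate 2, and 89.4% the other way, against at most 3.81% and 4.51% in 100 rotations. The Jaccard index of covered bases was 0.707, with 45.8 Mb shared. The 23278 peaks found in replicate 1 alone had a median fold of 3.33 and a width of 240 bp, and 6613 were found in replicate 2 alone. With the peaks of replicate 1 in 10 classes by −log10 p, every peak of the top 3 touched replicate 2, and 21.2% did in the lowest. Over 46880 matched peaks the fold enrichment had a Spearman correlation of 0.910 and a Pearson correlation of 0.930 on the log2 scale, across peaks, so without a p-value. The authors' replicated list held 54718 peaks, all with the coordinates of a pooled peak, and 86.8% touched peaks of both replicates. All 43996 pooled peaks with at least 50% of their length covered by each replicate were in it, and none of the 8479 peaks left out of it met that. If peaks had to overlap by 50% of both, the mean share touching between the replicates was 57.8% in place of 78.4%.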

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

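Peaks outside the chromosomes compared in the report were looked at only as data that no comparison used. Chromosome Y had 13 peaks in replicate 1 and 5 in replicate 2, and unplaced or unlocalised contigs had 15 and 12. They are listed here because each number is above 3, the limit for a count of 0. Called peaks are not such counts, so this is a rule for listing them and not a test. The labels say that both pools held embryos of both sexes, so a signal on chromosome Y has a source in the design. No technical or biological explanation was tested for these peaks.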

How the results depend on the processing

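The measures of height at the TSS, random lists drawn from genes with a promoter peak, strength matching, bases counted once against random blocks, promoter peaks against random lists matched on CpG, the middle of the peak as window centre, distal distance from any transcript, and promoter peaks at any transcript's start were alternatives chosen after the data were seen. Of 1335 values under alternatives, 1090 were counted as unchanged, 142 moved further, 41 lost a call, 14 gained one and 48 reversed. Unchanged meant the same direction and side of the threshold, or a move smaller than the spread of the replicates where available. A mean of both replicates always moves by less than their SD when either is left out, so those values could not test robustness. Counts and correlations had no such spread and were judged by other limits. For the overlap of replicates, the spread was that between the shares in each direction. The 1090 therefore includes values fixed in advance and is not a measure of robustness. Of 99 values for the 11 lists with longer coverage under alternatives set beforehand, 95 kept their call, and the 4 that lost it were all atrial. No paired analysis was possible because there is only 1 group. Depth is unknown, so what it limits cannot be given. The cause of each change below was not tested unless stated.

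The main values moved as follows. The overlap of replicates was 57.8% with 50% of both peaks required. The correlation of fold was 0.934 with −log10 p in its place and 0.925 with 50% of both peaks. The promoter share was 33.4% at 2.5 kb and 40.5% with all transcripts, where the larger window or set itself adds promoter sequence, and 40.4% at −log10 q of at least 5. The heart median of distal motif ratios was 1.14 at a distal limit of 1 kb, 1.11 at −log10 q of at least 5, 1.12 in windows of 1 kb and 1.21 away from any transcript's TSS. Lists passing fell to 1 by height, and lists apart between replicates to 3 with strength matching, and to 3 with each base once in random blocks matched on strength. Lists with more promoter peaks fell to 7 against random lists matched on CpG. Without each replicate in turn, the promoter share was 24.2 to 30.1%, promoter genes 14352 to 14623, lists passing 10 to 11 by covered length and 11 to 11 by promoter peak, distal motif ratios 1.16 to 1.18 and gap ratios 0.970 to 1.10.

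Percentiles of covered length among random lists changed side as follows. With 5 kb windows they were 66.2 for epicardial, 22.3 for neural crest, 0.53 for other-lineage factors, 56.6 for hepatocyte, 49.6 for skeletal muscle and 0 for Hox genes. With 25 kb they were 46.7 for macrophage, 47.8 for neural crest and 48.3 for lung genes. Without CpG matching they were 5.07 for erythroid, 1.36 for macrophage, 49.2 for neural crest, 6.07 for skeletal muscle and 6.64 for kidney and gut genes. There, 4 lists in place of 1 passed as covered over less, the clustered olfactory receptor genes among them. At −log10 q of at least 5 they were 48.0 for other-lineage factors and 45.8 for Hox genes. Without each replicate they were 40.7 to 86.7 for other-lineage factors, 49.7 to 63.6 for kidney and gut and 32.8 to 52.6 for epicardial genes. By height they were 2.02 for cardiac factors, 33.8 for calcium, 42.1 for energy, 5.9 for endothelial, 45.2 for erythroid, 48.2 for macrophage, 1.35 for neural crest, 18.1 for cell cycle, 0 for other-lineage factors, 8.28 for lung, 33.3 for kidney and gut and 0 for Hox genes. Among promoter-peak genes alone skeletal muscle was at 14.2. The replicate ratio of olfactory receptor genes was at 97.2 with strength matching and 93.8 with each base once in matched blocks.

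Promoter peaks fell below the share of other genes in neuron genes (10 at 500 bp, 11 at −log10 q of at least 5) and Hox genes (24 and 21). Against random lists matched on CpG, promoter peaks changed side for erythroid (percentile 77.8), skeletal muscle (62.9), other-lineage factor (4.58) and Hox genes (0), where the matching itself changes the genes compared. Of the motif ratios first over 1 SD from 1, those of these patterns crossed 1: SRF (0.987 at −log10 q of at least 5, 0.991 in 200 bp), CTCF (0.963 in 200 bp, 0.730 in gaps of 300 to 1000 bp), AP-1 (0.921 in those gaps) and the neuronal E-box (1.04 in gaps of 100 to 300 bp). Gap ratios within 1 SD of 1 also fell below it in gaps of 300 to 1000 bp for GATA (0.911), TEAD (0.863), NKX2, ETS (0.746) and RFX (0.671), and for RFX in gaps of 100 to 300 bp (0.992).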

Other observations

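The counts of wide domains, the comparison of height with length, the tests of lung tissue, of the composition of MEF2 matches, of patterns without CpG and of matches beside the summit were chosen only after the results were seen, as were the blocks with each base counted once. The test on fold and width of peaks was added after strength matching had been seen.

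The heart lists stood out by length more than by height. By the highest fold of a peak at the TSS, 1 of the 6 heart lists exceeded its random lists, contractile genes with a median of 18.7 against 0 (permutation adjusted p = 0.0250). Among genes with a promoter peak only, 5 of 6 were longer and 0 higher or lower. Other-lineage factors were lower (10.7 against 27.5, permutation adjusted p = 0.0025), and Hox genes, whose clusters the random lists do not match, had 6.36 against 27.9. A domain of over 5 kb lay on the TSS of 824 genes (3.79%). These included 20 of 27 cardiac factors, 13 of 25 contractile, 17 of 32 signalling, 9 of 23 calcium, 5 of 10 ventricular, 9 of 25 endothelial, 6 of 23 energy, 5 of 24 housekeeping and 4 of 16 fibroblast genes. Among Hox genes there were 2 of 39 and among other-lineage factors 0 of 30.

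In the heart muscle, endothelial, smooth muscle, fibroblast, epicardial and signalling lists, 13 members had no promoter peak in both replicates. A peak in both replicates at another annotated start was found for 46.2% of them (6 of 13, against 10.6% of other genes without one), among them Mef2c at 19439 bp and Mb at 28707 bp. These 6 have 3 (Krt19) to 27 (Mef2c) annotated starts, and the members without such a peak 1 (Nppa) to 8 (Msln). More starts give more places for a peak, and the number of starts was not matched. A pooled peak at the gene's 5' end was found for 30.8% (4 of 13, among them Nppa and Cdh5, against 3.37%). All 4 had a promoter peak in replicate 1 and none in replicate 2. The pooled list includes the alignments of replicate 1, so a pooled peak cannot tell a missed peak from an absent one. Of all genes, 7026 had a promoter peak in neither replicate and 350 in replicate 1 alone, so the low share of other genes was largely set beforehand. Neither share passed the 50% set in advance, and each covers only part of the 13. Both are above other genes, but the first contrast was not matched on the number of starts and the second cannot decide on a missed peak. A different start in use and a peak missed in 1 replicate therefore cannot be told apart as the main source. Sln, Msln and Upk3b have neither a peak at another start nor a pooled peak, and no biological explanation was tested.

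Hox, lung and other-lineage factor genes were covered over less length in replicate 2. With random lists matched on strength they stayed at percentiles 0, 0.01 and 0.1, and with each base counted once in matched blocks at 1.51, 0 and 0.15, where Hox genes make only 9 blocks. Strength averaged over a window does not match each peak, and with random peaks matched on fold and width Hox genes (4.93, 85 peaks) and other-lineage factors (2.85, 94 peaks) lay inside the central 95%, so weak or narrow peaks lost in replicate 2 are a candidate explanation that stays open for both. Lung genes stayed below (0.4, 23 peaks), outside what such a loss predicts. However, the list was picked for its extreme ratio, and signalling genes also lay outside, on the other side (98.05). Sftpc (6400 bp in replicate 1 and 3555 bp in replicate 2) and Foxa1 (6122 and 3409 bp) carried much of the lung difference. Such a loss is therefore not excluded there either. Lung tissue in the pool of replicate 1 stays open too: 0 of 6 lung epithelial genes had a promoter peak there, but the share of lung tissue that would give a called peak is unknown. No biological explanation was tested.

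CTCF and MEF2 matches were dense in gaps between distal peaks. Against 200 patterns with the same letters in random order, or as many as had matches, the CTCF ratio was at percentile 100, also when none of the patterns could hold a CpG, which argues against base composition. The MEF2 ratio was at 48 in replicate 1 and 90 in replicate 2 (58.5 and 92 without CpG), so composition may account for it. A place between marked nucleosomes stays open for both, since the contrast of matches beside and at the summit restates profiles already seen. For CTCF it was at percentile 100. For MEF2 it was at 60.5 and 70, but its matches were denser beside the summit in both replicates (ratios 1.61 and 1.60), so being within the range of patterns with the same letters does not exclude that place. No biological explanation was tested, as the design has 1 group.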
